A study of Mus musculus with 12 samples.

How the data were processed

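Gene expression was measured in 12 arrays of mouse myeloid cells, in 6 groups of 2. HoxB8-ER cells are bone marrow progenitors immortalized by HOXB8 fused to the estrogen receptor's ligand-binding domain, which holds them as dividing promyelocyte-like cells while estradiol (0.5 µM) is present. Removing estradiol lets them become neutrophils over 6 days. The groups were wild-type and Ezh2-null undifferentiated cells, neutrophils made from each, and wild-type neutrophils given GSK343, an inhibitor of the histone methyltransferase EZH2, or its vehicle. The sample labels give GSK343 at 0.5 µM for 9 days and the series text gives 1 µM, so the dose is not settled here. The 2 genotypes came from bone marrow of littermates. The labels do not say how many lines were made or whether replicates were separate cultures, so genotype cannot be separated from cell line, and p-values measure only the spread between these arrays, which may be technical.

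Total RNA (250 ng) was hybridised to the Affymetrix Mouse Transcriptome Array 1.0, per the labels' protocols. The deposited values are log2 signals per transcript cluster or control probe set, as their range shows. The submitters' processing notes name the Affymetrix Expression Console and the Transcriptome Analysis Console. Versions, the summarisation method, background correction and genome build are not given in the sources used here, so no coordinates are printed. The medians over clusters lay between 4.54 and 4.65 on the 8 genotype arrays and between 3.88 and 3.96 on the 4 drug arrays. The 2 ranges of array numbers therefore look separately normalized, and values are compared within a range except where stated. The highest value, 19.93, was shared by 3 of the drug arrays and looks like a ceiling.

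The table held 72688 entries, of which 6732 were control probe sets and were left out of the tests. Of the 65956 transcript clusters tested, 31258 carried 1 gene symbol, 1492 carried several and 33206 carried none in the annotation given. Symbols were updated by Entrez ID through a RefSeq gene table (assembly GRCm38.p6), which matched 22818 of the 1-symbol clusters and changed 1152 symbols. Genes were named only from 1-symbol clusters, 30702 genes in all. For the 441 genes with several clusters, the cluster with the highest mean over all arrays stood for the gene.

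Array background was set at the 95th percentile of 23 antigenomic control probe sets and lay between 4.83 and 5.79 on the log2 scale. Between 28.8% and 43.4% of clusters lay above it. The median of the 5222 negative control probe sets lay above this background on most arrays, such as wild-type neutrophil array 2 (6.60 against 5.47). It lay below on Ezh2-null undifferentiated array 1 (5.39 against 5.79) and GSK343 array 1 (5.19 against 5.20). Statements about background, and the bounds on folds, therefore depend on this choice of limit. A limit set from the negative controls was not run. Arrays of 1 group correlated with each other at Pearson r of 0.984 to 0.995 across clusters. GSK343 array 2 correlated more closely with an array of another group (0.9947) than with its replicate (0.9935). Both Ezh2-null undifferentiated arrays reached 0.982 with an array of another group, against 0.984 with each other. With 2 arrays per group, the number of arrays limits the precision. Where a gene lay at or under background on every array of the dimmer group, the fold is written as "at least": the brighter group's mean was set against the dimmer group's mean of, per array, the higher of the background and the gene's own signal. Interaction values are fitted differences and are not bounded in this way. SDs are over the 2 arrays of a group.

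All 12 arrays were fitted together on the log2 scale with limma 3.58.1 (R 4.3.3, lmFit and eBayes, 6 group means). The residual degrees of freedom were 6 and the prior degrees of freedom 3.06. A cluster was called when its Benjamini-Hochberg adjusted p was under 0.05, and counts with at least a 2-fold change are given beside. Contrasts were genotype at each stage, GSK343 against vehicle, differentiation in each genotype, and the interactions of genotype with stage and of genotype label with drug. The contrasts of genotype in neutrophils, genotype in undifferentiated cells and drug share no arrays. Adjusted p-values are from limma unless another tool is named.

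A total of 29 gene lists were tested with camera (preset correlation 0.01, adjusted over the lists of a contrast), with camera's correlation estimated from the data, and with fry. They covered Polycomb subunits, HOX and developmental genes, fetal and germline genes, CDK inhibitors, granule, oxidase and receptor genes of neutrophils, progenitor, cell cycle, interferon, inflammatory, sterol and sex chromosome genes, and markers of 9 groups of other cell types. The median, mean and camera direction of a list differed in sign in 44 of the 203 list tests, none of which camera called. For the lists described, the counts "adjusted over the list alone" use only the list's members. Per contrast, the named genes were Ezh2, up to 10 rising and 10 falling genes of largest change whose groups did not overlap, and up to 2 called members per list and direction, or where none was called up to 2 of its brightest members as values. For shared changes, up to 10 genes per direction were taken, and for interactions up to 5. Predicted, microRNA, snoRNA, olfactory, vomeronasal, histone and receptor-segment symbols were left out. The groups, contrasts, lists and this rule, and most alternative settings, were fixed before the data were examined.

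Alternatives were a filter on dim clusters, 1-symbol clusters only, further quantile normalization, median centring, a trended robust variance, array weights, fits with fewer arrays, the replicate number as a block, other thresholds and leaving out each array. When 1 array was left out, the lone array of its group was assumed to vary like the other groups. Crossed replicate numbers, quantile normalization within each array range, a background-based baseline, list medians without 1 array and tests of 1 contrast's calls in another were chosen after seeing the data.

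The tests were tried on simulated arrays with 200 of 65956 clusters changed, 50 of each size. For the genotype contrast in neutrophils, 38% of 2-fold, 88% of 4-fold and 98% of 16-fold changes were recovered, with 3 false calls. For the genotype contrast in undifferentiated cells, 46% of 2-fold and 96% of 4-fold changes were recovered, with 5 false calls. For GSK343 against vehicle, 46% of 2-fold and 98% of 4-fold changes were recovered, with 6 false calls, and for wild-type differentiation 34% and 92%, with 9. Of 20 simulated sets shifted by 0.5 log2 in the neutrophil genotype contrast, camera with either correlation and fry each called 20, and none of 80 unshifted sets. The simulated noise was independent between clusters, so these counts do not show how the tests behave on lists of correlated genes. The adjusted p cutoff also depends on how many clusters change. The recovered shares therefore hold for 200 changed clusters, not for contrasts with 1 or 7791 calls. A simulation without any genotype effect on differentiation gave 0 interaction calls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.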

Results

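The deposited array values covered 65956 transcript clusters in 2 arrays of each of 6 groups. They addressed what loss of EZH2, the catalytic subunit of Polycomb repressive complex 2 (PRC2), does to gene expression in myeloid progenitors and in the neutrophils made from them, and whether inhibiting EZH2 during differentiation does the same. The first principal component held 59.3% of the variance between arrays, the second 24.6% and the third 6.55%. These were taken over both array ranges. On the first component the drug arrays lay between −185 and −156, and untreated wild-type neutrophils at −43.5 and −29.7, so its share mixes array range with biology.

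Ezh2 (cluster TC0600002200.mm.1) was first compared in every group, as a check of the genotype labels. In undifferentiated cells, Ezh2 signal fell from 11.61 ± 0.06 in wild-type to 9.27 ± 0.25 in Ezh2-null arrays (log2, SD, n = 2 each), a drop of 5.07-fold that passed the test (log2 fold change −2.34, SE 0.155, adjusted p = 5.5e-05). In wild-type cells, Ezh2 fell by 3.29 log2 units on differentiation (SE 0.155, adjusted p = 1.23e-06), to 8.33 ± 0.02. In neutrophils labelled Ezh2-null, the signal was 8.88 ± 0.19, so Ezh2 was not lower than in wild-type neutrophils (difference 0.55, SE 0.155, adjusted p = 0.0501). The cluster summarises the whole gene and the labels do not say which exons were deleted, so the transcript level does not settle the genotype of those neutrophils. They are called "neutrophils labelled Ezh2-null" throughout, and each direction drawn from them rests on the label. The effect of genotype on Ezh2 differed between stages by 2.89 log2 units (SE 0.219, adjusted p = 0.000186). With GSK343, which inhibits the enzyme and need not lower its transcript, Ezh2 was 9.31 ± 0.03 against 8.90 ± 0.17 with vehicle (adjusted p = 0.736).

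**Figure D1:**
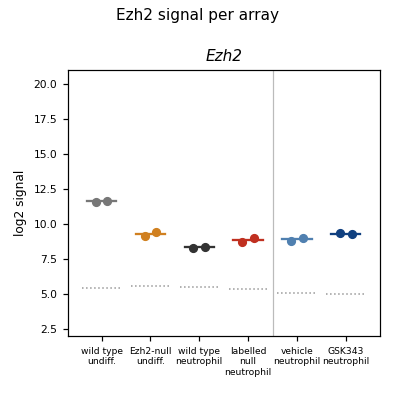
Ezh2 signal (log2) on each of the 12 arrays in the 6 groups, with a bar at each group mean and a dotted line at the group's mean array background. The wild-type undifferentiated arrays stand highest, at 11.61 on average, and the neutrophils labelled Ezh2-null (8.88) lie no lower than wild-type neutrophils (8.33).

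Differentiation of wild-type cells replaced one granule gene set by another. Retnlg, a resistin-like protein of mature neutrophils, rose at least 7053-fold (log2 fold change 13.50, SE 0.319, adjusted p = 4.19e-08). Ltf, which encodes lactoferrin of specific granules, rose at least 6115-fold (13.18, SE 0.389). The stefin genes Stfa2l1 (at least 12930-fold) and Stfa1 (at least 6227-fold) and the calprotectin genes S100a8 (12.73 log2 units) and S100a9 (12.77) rose as well. Muc13 fell at least 2268-fold (SE 0.24, adjusted p = 2.96e-08). The mast cell protease gene Cpa3 (−11.17, SE 0.224) and the primary granule genes Ctsg (−10.56, SE 0.679) and Mpo (−10.21, SE 0.579) fell as well.

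Gene lists moved along the same lines in wild-type differentiation. All 14 secondary granule genes rose (14 adjusted over the list alone, median 8.20, camera adjusted p = 2.26e-14), including Ngp at 12.64 and Chil3 at 13.37, while 8 of 10 primary granule genes fell and 1 rose (8 and 1 adjusted over the list alone, median −5.26, adjusted p = 6.18e-05). All 7 NADPH oxidase genes rose (7 adjusted over the list alone, median 3.33, adjusted p = 6.87e-07), led by Cybb, the oxidase's catalytic subunit, at 12.16 (SE 0.227, at least 3626-fold). Of 15 migration receptors 13 rose (13 adjusted over the list alone, median 3.14, adjusted p = 1.66e-09), and 8 of 10 gelatinase granule genes, among them Mmp9 at least 1631-fold (8 adjusted over the list alone, median 7.33, adjusted p = 1.03e-08). With an estimated correlation, these lists gave adjusted p = 0.127, 0.225, 0.127, 0.127 and 0.124. Innate recognition receptors rose (20 of 22, 20 adjusted over the list alone, median 3.33, adjusted p = 0.0386 with an estimated correlation), with Tlr7 at least 285-fold higher. Progenitor genes fell (16 of 20 and 1 rise, 16 and 1 adjusted over the list alone, median −2.66, adjusted p = 0.0322 with an estimated correlation), with the stem cell factor receptor Kit at −7.45 and Myb at −7.39. Cell cycle genes fell (24 of 26, 26 adjusted over the list alone, median −3.34, camera adjusted p = 1.46e-13), with the replication helicase gene Mcm2 at −5.54, although adjusted p = 0.247 with an estimated correlation.

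Other lists also shifted in wild-type differentiation. Monocyte and macrophage markers rose (13 of 19, 13 adjusted over the list alone, median 3.68, camera adjusted p = 2.08e-07), with the M-CSF receptor gene Csf1r at 9.41, and adjusted p = 0.144 with an estimated correlation. PRC2 genes fell in 8 cases and rose in 3 of 12 (8 and 3 adjusted over the list alone, median −1.34, adjusted p = 0.0202), with Rbbp7 at −3.13 and the Ezh2 paralog Ezh1 at 2.72. PRC1 genes fell in 10 cases and rose in 1 of 17 (10 and 2 adjusted over the list alone, median −0.64, adjusted p = 0.00326). The estimated correlation gave adjusted p = 0.129 for PRC2 and adjusted p = 0.133 for PRC1. Granulocyte factors (8 up, 2 down of 11, 8 and 2 adjusted over the list alone, median 1.96), inflammatory genes (12 up, 2 down of 20, 12 and 3 alone, median 1.41), interferon-stimulated genes (11 of 23 up, 13 alone, median 1.04) and sterol genes (8 of 16 down, 10 alone, median −1.51) were called by camera too. For these, the estimated correlation gave adjusted p = 0.278, 0.127, 0.629 and 0.638. On interferon-stimulated genes the 2 wild-type neutrophil arrays stood apart (median gap 1.15), by more than that list's median of 1.04. Camera called 15 of 29 lists, 2 of them also with an estimated correlation. In all, 16664 clusters changed (8604 up, 8060 down, and 11533 by at least 2-fold). With 1-symbol clusters only, the balance turned, to 4092 up and 6308 down. The balance depended on scaling, with 7505 up and 8666 down after further quantile normalization and 7638 and 8779 after median centring, and on the arrays, with 6231 up and 6555 down without wild-type undifferentiated array 1 and 6145 and 6398 without array 2.

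In Ezh2-null undifferentiated cells a set of genes was higher than in wild type, several of them at background in wild-type progenitors, and primary granule genes were lower. Angptl7, a secreted angiopoietin-like protein, was at least 207.5-fold higher in Ezh2-null cells (13.14 ± 0.26 against 4.35 ± 0.09, log2 fold change 8.79, SE 0.154, adjusted p = 2.19e-08). Smo, the Hedgehog pathway receptor, rose by 6.21 log2 units (SE 0.138, adjusted p = 9.42e-08), and Tbx15, a developmental transcription factor, at least 30.9-fold (SE 0.252, adjusted p = 7.49e-06). Golm2 (5.90), Spats2 (at least 40.8-fold) and the Wnt co-receptor gene Ryk (at least 33.1-fold) rose too. Adgrg7 fell at least 110-fold (SE 0.173, adjusted p = 8.16e-08), and Mmp8 (−6.43, SE 0.478) and the myeloid genes Ms4a3 (−6.86), Ccr2 (−6.71), Clec5a (−5.91) and Hk3 (−5.90) also fell.

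Among the lists, primary granule genes fell most broadly in Ezh2-null undifferentiated cells (6 of 10, 7 adjusted over the list alone, median −1.86, camera adjusted p = 2.26e-09; adjusted p = 0.588 with an estimated correlation). The 2 Ezh2-null arrays stood apart on this list (median gap −0.65), as Ctsg (13.57 and 10.87) shows. Limma called 2 falls without wild-type undifferentiated array 1 and 3 without array 2, while the median stayed near −1.86 and −1.87. Small parts of the Polycomb target lists rose: 5 of 52 developmental transcription factors (6 adjusted over the list alone, median 0.04), among them Foxa1 (at least 7.51-fold), 3 of 33 HOX genes (6 alone, median 0.05), among them Hoxc10 (at least 1.45-fold), and 2 of 14 fetal genes (2 alone, median 0.10), led by Lin28b (at least 5.89-fold, SE 0.174, adjusted p = 7.26e-06). Camera gave adjusted p = 0.0449, 0.0347 and 0.0449 for these lists, and adjusted p = 0.962, 0.743 and 0.779 with an estimated correlation. Of 17 PRC1 genes 3 rose (5 up and 1 down adjusted over the list alone, median 0.20), with Bmi1 at 1.71 and Phc1 at 0.94. Innate receptors fell in 4 of 22 cases (7 down and 2 up alone, median −0.31), with Clec4d at −3.13 and Tlr4 at −2.69, and monocyte markers in 3 of 19 (5 alone, median −0.02). Camera gave adjusted p = 0.0235, 0.0101 and 0.0235 for PRC1, innate and monocyte lists, and adjusted p = 0.645, 0.645 and 0.847 with an estimated correlation. The camera calls of developmental and fetal genes ended with the replicate number as a block, and those of PRC1, HOX and fetal genes when dim clusters were left out. That of monocyte markers ended with fry in place of camera. Fetal genes gave 1 rise without wild-type array 1, wild-type array 2 or Ezh2-null array 2, and monocyte markers 1 fall without wild-type array 1.

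The other 22 lists were not called by camera in undifferentiated cells. Within them, the proteinase gene Prss34 (2.84) and Hlf, a stem cell transcription factor (2.79), rose, while the basophil protease gene Mcpt8 fell by 4.67 log2 units (SE 0.152, adjusted p = 1.09e-06). None of the 26 cell cycle genes was called (median −0.19), with Mki67 at −0.36 (adjusted p = 0.811). The Ezh2-null arrays differed on cell cycle and sterol genes (median gaps −0.88 and −1.71), and without array 1 limma called 4 and 3 of them lower. In total 1969 clusters differed by genotype in undifferentiated cells (1087 up, 882 down; 1353 by at least 2-fold). This count fell to 962 without wild-type undifferentiated array 1, to 1060 without array 2, and to 351 when only the 4 compared arrays were fitted. Without Ezh2-null array 2 the balance turned, to 1211 up and 1320 down. Of the 70 named calls, several were lost without 1 or another array. Most of those lost are not described above, such as Cd93, Cebpa, Gata2, Hmga2 and Runx1. Among the genes described above for this comparison, only Ctsg was lost, at −4.09 and −3.92 without wild-type undifferentiated arrays 1 and 2. With only the 4 compared arrays 37 were lost, among them Ms4a3, Bmi1, Phc1, Clec4d, Tlr4, Hlf and Prss34.

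Neutrophils labelled Ezh2-null held high levels of mast cell and erythroid transcripts. Tpsb2, a mast cell tryptase gene, stood at 16.45 ± 0.01 against 4.47 ± 0.16 in wild-type neutrophils, at least 1987-fold higher (log2 fold change 11.97, SE 0.287, adjusted p = 5.48e-08). The mast cell carboxypeptidase gene Cpa3 was 2832-fold higher (19.10 ± 0.02 against 7.64 ± 0.54, SE 0.224, adjusted p = 1.36e-08). Car2, a carbonic anhydrase of red cells, rose by 11.01 log2 units (SE 0.189, adjusted p = 7.37e-09). Rhag, part of the red cell Rh complex, was at least 522-fold higher (adjusted p = 2.83e-08), and the erythrocyte genes Aqp1 (at least 408-fold) and Ermap (at least 354-fold) rose as well. Further rises were seen for Aldh1a1 (at least 134-fold), the chymase gene Cma1 (at least 151-fold), granzyme B (Gzmb, at least 119-fold) and Cyp11a1 (at least 101-fold).

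Myeloid genes were lower in neutrophils labelled Ezh2-null. Plbd1, a granule phospholipase-like protein, fell by 8.63 log2 units (from 12.63 ± 0.97 in wild type, SE 0.391, adjusted p = 2.94e-06), which is at least 155-fold. The heparanase gene Hpse (−6.55, SE 0.433), Serpinb10 (−5.74, SE 0.515), the transcription factor gene Maf (−5.73, SE 0.538), Flot2 (−5.54) and Lrg1 (−5.53), a granule glycoprotein gene, fell by over 5 log2 units each.

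Several sets of genes rose together in neutrophils labelled Ezh2-null. Eosinophil, basophil and mast cell markers rose in 13 of 17 cases (13 up and 2 down adjusted over the list alone, median 1.93, camera adjusted p = 2.12e-10; adjusted p = 0.0105 with an estimated correlation), including Mcpt8 (at least 65.2-fold) and the IgE receptor genes Ms4a2 (at least 24.3-fold) and Fcer1a (at least 4.91-fold). The eosinophil genes Prg2 (0.47, adjusted p = 0.714) and Epx (at background in both, adjusted p = 0.131), named after their values were seen, were not called. Erythroid and megakaryocyte markers rose in 7 of 12 cases (7 alone, median 1.89, camera adjusted p = 2.41e-07; adjusted p = 0.102 with an estimated correlation), among them the erythroid factor gene Klf1 (at least 12.5-fold, SE 0.2), Alas2 (at least 6.83-fold) and Gata1 (at least 1.89-fold). Haemoglobin genes other than Hbb-y had no cluster of their own and were not analysed here. Cell cycle genes rose in 24 of 26 cases (25 alone, median 2.74, camera adjusted p = 9.39e-20; adjusted p = 0.304 with an estimated correlation), led by the replication licensing genes Cdc6 at 4.22 (SE 0.194) and Mcm2 at 3.99 (SE 0.204). Interferon-stimulated genes rose in 18 of 23 cases (22 alone, median 2.51, camera adjusted p = 5.25e-15; adjusted p = 0.304 with an estimated correlation), led by Usp18 at 5.71 (SE 0.606) and Ifit1 at 5.43 (SE 0.428). The 2 wild-type neutrophil arrays stood apart on this list (median gap 1.15), as Ifit1 (6.42 and 8.06) and Usp18 (7.22 and 9.11) show. The labelled-null arrays did too (median gap 0.86). The list's median was 1.83 without wild-type array 1, 3.20 without array 2, 2.96 without labelled-null array 1 and 2.10 without array 2. Without 1 array, medians ranged from 1.44 to 2.28 for the mast cell list, 1.87 to 1.95 for erythroid markers and 2.43 to 3.05 for cell cycle genes.

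**Figure D2:**
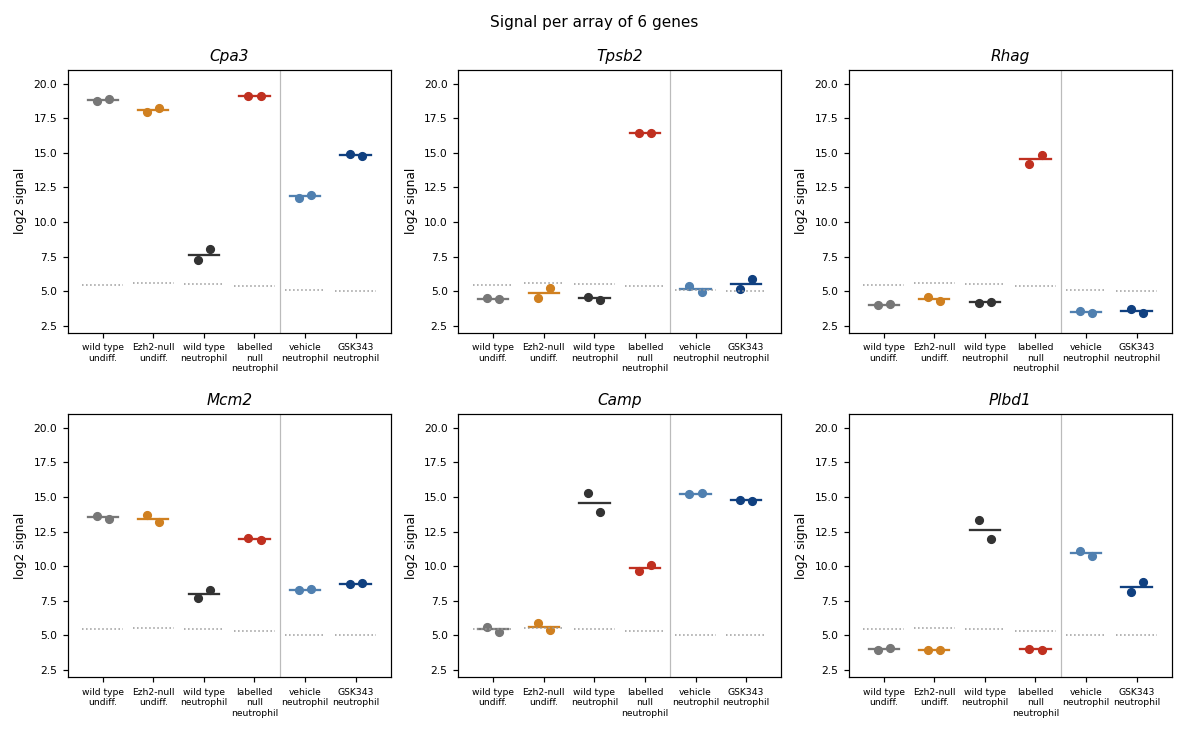
Signal (log2) of Cpa3, Tpsb2, Rhag, Mcm2, Camp and Plbd1 on each array in the 6 groups, with bars at group means and dotted lines at the mean background; a vertical line parts the genotype from the drug arrays, which look separately normalized. Tpsb2 averages 16.45 in neutrophils labelled Ezh2-null and 4.47 in wild-type neutrophils.

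Neutrophil effector lists were lower in neutrophils labelled Ezh2-null. Secondary granule genes fell in 9 of 14 cases (9 adjusted over the list alone, median −1.78, camera adjusted p = 2.41e-07), with the cathelicidin gene Camp at −4.74 (9.87 ± 0.34 against 14.60 ± 1.01, SE 0.394, adjusted p = 0.000103) and Cd177 at −4.47, whereas Lyz2 (−0.09) and Mmp8 (−0.40) were not called. NADPH oxidase genes fell in 2 of 7 cases (4 alone, median −0.84, adjusted p = 0.000451), with Cybb at −2.39 (SE 0.227, adjusted p = 0.000207) and the proton channel gene Hvcn1 at −1.59. Gelatinase granule genes fell in 4 of 10 (5 down and 1 up alone, median −0.66, adjusted p = 0.0341), with the histone deiminase gene Padi4 at −3.25. Migration receptors fell in 6 of 15 (9 alone, median −1.04, adjusted p = 0.000256), with the C5a receptor gene C5ar1 at −2.34. Innate receptors fell in 10 of 22 and rose in 1 (13 and 2 alone, median −0.99, adjusted p = 0.000206), with Tlr7 at −2.77 and the beta-glucan receptor gene Clec7a at 1.72. Monocyte markers fell in 7 of 19 (14 alone, median −1.52, adjusted p = 1.59e-05), with Mertk at −2.88 and C1qb at −2.58. Granulocyte factors fell in 4 of 11 (7 down and 1 up alone, median −1.18, adjusted p = 0.0074). With an estimated correlation these lists gave adjusted p = 0.304, 0.304, 0.415, 0.373, 0.304, 0.304 and 0.397. Without 1 array the medians of these lists stayed negative but moved. That of gelatinase genes ranged from −1.07 to −0.38 and that of granulocyte factors from −1.58 to −0.72. The number of falls called by limma moved too. Secondary granule genes, on which the 2 wild-type arrays differed (median gap −0.83), gave 6 without wild-type neutrophil array 1 or labelled-null array 2 (medians −1.46 and −1.62), and oxidase genes 3 without labelled-null array 1. Gelatinase genes gave 2 without wild-type neutrophil array 1, wild-type array 2 or labelled-null array 2, migration receptors 3 without wild-type array 1 and 2 without labelled-null array 2, and innate receptors 6 without labelled-null array 2. Monocyte markers, with a wild-type gap of 0.80, gave 4 without wild-type array 2, and granulocyte factors 1 without wild-type array 1, 5 without wild-type array 2, 2 without labelled-null array 1 and 0 without labelled-null array 2. Among granulocyte factors, Cebpe, which drives specific granule genes, was at −1.77 (adjusted p = 0.0318). Its call ended without labelled-null neutrophil array 1 (adjusted p = 0.0561), array 2 (adjusted p = 0.2) or wild-type neutrophil array 1 (adjusted p = 0.105).

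The remaining 18 lists were not called by camera in this comparison. Progenitor genes went both ways (6 up, 3 down of 20; 8 and 4 adjusted over the list alone), with Kit at 5.35 (SE 0.253) and Gata2 at 4.15 above wild type, and Erg at −3.97 and Prom1 at −3.52. PRC2 genes (2 up, 2 down of 12; 5 and 3 alone) included Rbbp7 at 1.40, Suz12 at 1.10, Phf1 at −2.35 and Ezh1 at −1.22, and PRC1 genes (4 up, 2 down of 17; 5 and 4 alone) included Bmi1 at 2.32. Cell cycle inhibitor genes (2 up, 2 down of 7; 4 and 3 alone) included Cdkn2a at 2.35 (SE 0.218) and Cdkn1a at −4.27 (SE 0.63). Of 52 developmental transcription factors, Tbx15 (at least 9.54-fold) and Foxa1 (at least 1.55-fold) rose (2 alone). Of 33 HOX genes, Hoxc4 rose (at least 1.94-fold) and Hoxa6 fell at background level (1 and 1 alone). Fetal genes (2 up, 2 down of 14; 3 and 2 alone) included Hmga2 at 1.84. The primary granule list held 1 rise, Mpo at 3.48 (SE 0.579, adjusted p = 0.0044), and 1 fall (1 and 1 alone). Inflammatory genes rose in 5 of 20 cases (6 up and 2 down alone, median 0.40). Dendritic markers gave 2 rises and 1 fall of 15 (2 and 2 alone), B lymphoid 2 and 1 of 13, T and NK 1 rise of 17 (Gzmb), fibroblast and endothelial 1 rise of 11 (Pdgfrb, 1.37), germline 1 rise of 20 (Ddx4, at background in wild type) and sex chromosome genes 1 fall of 5 (Kdm5d, −0.78; 2 alone). The 16 sterol, 13 neuronal and 14 epithelial genes gave no call (medians −0.10, 0.05 and −0.02). These small counts moved without 1 array. Without wild-type neutrophil array 1, limma called inflammatory genes in 0 cases (median 0.27), 2 rises and 0 falls of PRC1 genes, and 1 and 1 each of cell cycle inhibitors and B lymphoid genes. Without wild-type array 2 it called 2 and 2 of PRC1, 5 and 2 of inflammatory, 3 and 0 of dendritic and 1 and 0 of B lymphoid genes. Without labelled-null array 1 it called 3 and 0 of PRC1, 1 and 1 of cell cycle inhibitor, 3 and 0 of inflammatory (median 0.21), 2 and 0 of dendritic, 2 and 0 of T and NK, and 1 and 1 of fibroblast and endothelial genes. Without labelled-null array 2 it called 2 and 0 of PRC1, 1 and 1 of cell cycle inhibitor, 2 and 0 of primary granule, 1 and 2 of dendritic and 1 and 0 of B lymphoid genes. Fetal genes gave 1 fall without any of the first 3 arrays and 0 without labelled-null array 2. Ddx4 was not called without any 1 of the 4 arrays (adjusted p = 0.0716 to 0.0967), Pdgfrb not without labelled-null array 2 (adjusted p = 0.118) or wild-type neutrophil array 1 (adjusted p = 0.105), and Hoxa6 not without the latter (adjusted p = 0.0535).

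In total 7791 clusters differed between neutrophils labelled Ezh2-null and wild-type neutrophils (4455 up, 3336 down; 5004 by at least 2-fold). The count was 4023 without labelled-null array 2 and 4922 without wild-type neutrophil array 1. Camera called 11 of the 29 lists, 1 of which (eosinophil, basophil and mast cell markers) also held with an estimated correlation. Of 94 named calls, 22 were lost when 1 or another array was left out, and 17 with only the 4 compared arrays, among them Mpo, Cebpe and Pdgfrb.

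**Figure D3:**
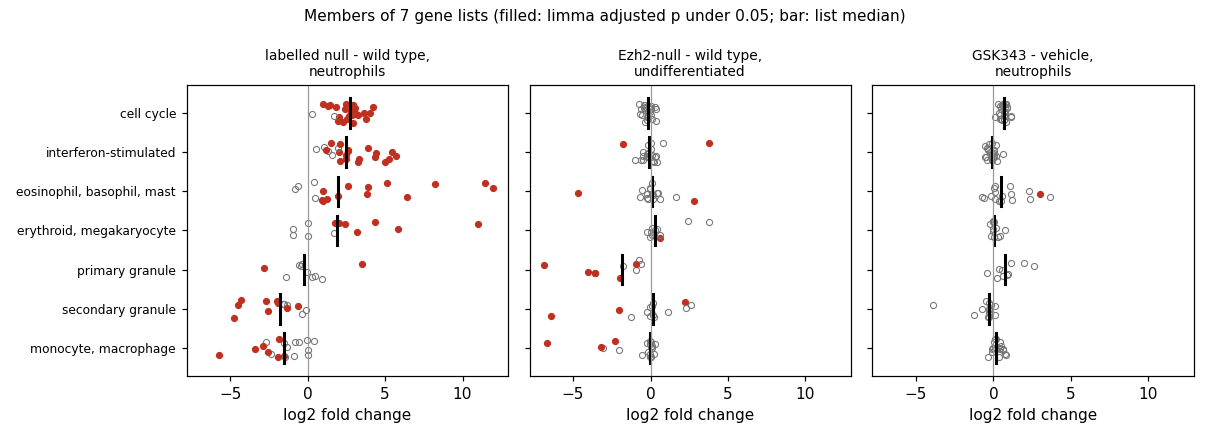
Log2 fold changes of the members of 7 gene lists in 3 comparisons (Ezh2-null against wild-type undifferentiated cells, neutrophils labelled Ezh2-null against wild-type neutrophils, GSK343 against vehicle), 1 point per gene, filled where the limma adjusted p was under 0.05, with a bar at the list's median. In neutrophils, cell cycle and interferon-stimulated genes have medians of 2.74 and 2.51, and secondary granule genes −1.78.

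The series title speaks of ectopic expression, so the wild-type baseline of the higher genes was examined in the vehicle-treated wild-type neutrophils, which took no part in the genotype contrast. Among clusters higher in neutrophils labelled Ezh2-null, 889 of 4455 lay below the median of all clusters in vehicle-treated cells. By definition 50% of all clusters lie below that median; the difference from that share was not tested. Among lower clusters the number was 195 of 3336 (5.85%), but a cluster can be called lower only from a level above the floor. The planned test of higher against lower clusters is therefore fixed in part by the calls, and its p is not given. Of the 3008 clusters called at least 2-fold higher, 716 were at background on all 4 wild-type and vehicle neutrophil arrays. Of these 716, 377 carried 1 gene symbol. The wild-type arrays are the controls of this contrast, so a low level on them is fixed in part by the call. Among all clusters, 68.5% were at background in vehicle-treated and 63.0% in untreated wild-type neutrophils. Of the 716, 570 were at background in wild-type undifferentiated cells too. The matching share of all clusters was not computed, and neither count was tested.

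Genes changed in the same direction at both stages were next counted. Among those higher in Ezh2-null cells and in neutrophils labelled Ezh2-null were Spire1, an actin nucleator gene (4.76 log2 units in undifferentiated cells and at least 59.7-fold in neutrophils), Gphn (5.11 log2 units and at least 13.4-fold), Prxl2a (3.53 and 5.59 log2 units) and Smo (6.21 and 3.97). At background in wild type at both stages were Cecr2 (at least 7.61-fold and 16.4-fold higher), Ryk (33.1 and 15.8), Tbx15 (30.9 and 9.54) and the transporter gene Abcg2 (8.09 and 7.95). Serpinb10 (−5.33 and −5.74), Trem3 (−3.81 and −3.67), Gca (−4.89 and −3.20), B4galt6 (at least 7.90-fold, and −5.01) and Slc22a4 (at least 20.6-fold, and −3.74) were lower at both. In all, 514 clusters were higher at both stages, where independent lists would share 73.4, and 368 were lower at both (44.6). Opposite calls numbered 70 (115 expected). The expected numbers treat all 65956 clusters as equally likely to be called. Clusters that stay at background have little room to be called, so the expected numbers are likely too low. Across clusters, the log2 fold changes of the stages correlated at Pearson r = 0.33, without shared arrays. The shared count of 882 was 472 without wild-type undifferentiated array 1 and 497 without array 2.

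The difference by genotype label changed between stages for 2911 clusters (1824 up, 1087 down in neutrophils relative to undifferentiated cells). Cpa3 (12.17, SE 0.316, adjusted p = 1.43e-07), Tpsb2 (11.55), Mcpt8 (11.11), Car2 (11.06) and Rhag (9.93) led the rises, and Plbd1 (−8.55, SE 0.553), Angptl7 (−8.55, SE 0.217) and Maf (−5.95) the falls. Camera called 9 lists, among them cell cycle genes (20 of 26 up, 24 adjusted over the list alone, median 2.93, adjusted p = 1.65e-23) and interferon-stimulated genes (14 of 23 up, 18 up and 1 down alone, median 2.81, adjusted p = 1.87e-14). The estimated correlation gave adjusted p = 0.299 and adjusted p = 0.364 for them, and adjusted p = 0.0151 for eosinophil, basophil and mast cell markers (7 of 17 up, 10 alone, median 1.18). The count was 1511 without wild-type undifferentiated array 2, 1636 without array 1, and 1610 without labelled-null neutrophil array 2.

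Differentiation of cells labelled Ezh2-null induced neutrophil genes and mast cell genes such as Tpsb2. Retnlg rose at least 3615-fold (SE 0.319 on the log2 scale, adjusted p = 6.66e-08), and Mmp9 at least 1085-fold, while Tpsb2 rose at least 1896-fold (11.57, SE 0.287; in wild type 0.02, adjusted p = 0.973). The macrophage gene Gpnmb rose at least 908-fold, and at least 724-fold in wild type. Adgrl4 fell by 10.09 log2 units (SE 0.333, adjusted p = 2.24e-07), the progenitor receptor Flt3 was at −7.31 (SE 0.396) and Hlf at −7.50 (SE 0.244). Secondary granule genes rose in 13 of 14 cases (13 adjusted over the list alone, median 5.95, camera adjusted p = 3.22e-14; adjusted p = 0.0904 with an estimated correlation), and interferon-stimulated genes in 21 of 23 (21 alone, median 3.95, adjusted p = 4.76e-16; adjusted p = 0.125 with an estimated correlation). Cell cycle genes gave 2 rises and 8 falls of 26 (3 and 8 alone, median −0.34, adjusted p = 0.334), with Mcm3 at −2.31 and Tyms at −2.07. The 2 Ezh2-null undifferentiated arrays differed on this list by more than its median (median gap −0.88). Camera called 18 lists, of which innate receptors, progenitor genes, inflammatory genes and eosinophil, basophil and mast cell markers held with an estimated correlation (adjusted p = 0.0228, 0.0211, 0.0435 and 0.0211). Altogether 14799 clusters changed (7710 up, 7089 down; 9131 by at least 2-fold), and 7591 when only the 4 compared arrays were fitted. The balance turned with scaling, to 6233 up and 8428 down after further quantile normalization and 6730 and 8133 after median centring, and was 3299 and 5868 for 1-symbol clusters, and 5498 and 6285 without Ezh2-null undifferentiated array 1.

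Of the 16664 clusters changed in wild-type differentiation, 2011 (12.1%) changed less in cells labelled Ezh2-null by the interaction test and 182 (1.09%) changed more. The changes were smaller for 726 of 8604 rises (8.44%) and 1285 of 8060 falls (15.9%). These clusters were chosen by their wild-type change, and the same wild-type arrays enter the interaction with the opposite sign. Clusters changed only in cells labelled Ezh2-null, such as Tpsb2, were left out by this choice. The excess of smaller over larger changes is therefore fixed in part by the choice and was not tested. Among the genes of smaller rise were Camp (interaction −4.94, SE 0.558, adjusted p = 0.00157) and Cybb (−2.72, SE 0.321, adjusted p = 0.002), and among those of smaller fall Kit (4.31) and Cdc6 (4.19). In both genotypes 10187 clusters changed in the same direction and 169 in opposite directions, and the 2 sets of fold changes correlated across clusters at r = 0.80. The count of 2011 was 1058 without wild-type undifferentiated array 1, 978 without array 2, 1309 without wild-type neutrophil array 1 and 992 without labelled-null neutrophil array 2.

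**Figure D4:**
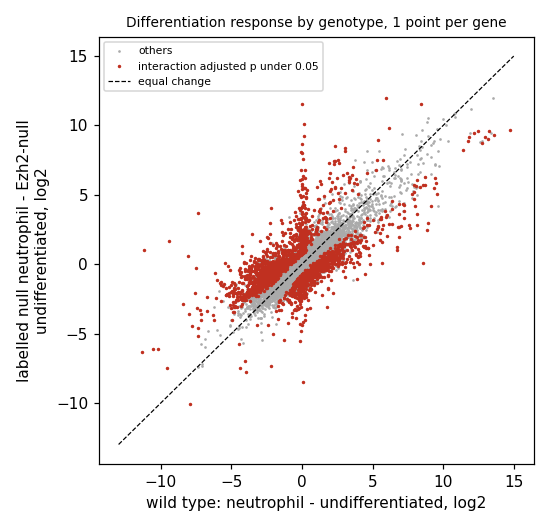
Log2 fold change on differentiation in wild-type cells (x axis) against that in cells labelled Ezh2-null (y axis), 1 point per gene; red points had an interaction adjusted p under 0.05 and the dashed line marks equal change. Most points follow the line (r = 0.80 over all clusters), and the red points lie away from it.

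With GSK343, Cpa3 was the 1 cluster called in wild-type neutrophils. It was 7.96-fold higher than with vehicle (14.84 ± 0.06 against 11.85 ± 0.12, log2 fold change 2.99, SE 0.224, adjusted p = 0.0187). The call ended without any 1 of the 4 arrays: adjusted p = 0.278 without GSK343 array 1, 0.0703 without array 2, 0.427 without vehicle array 1 and 0.354 without vehicle array 2. It also ended with only these 4 arrays fitted. Among eosinophil, basophil and mast cell markers, 1 of 17 was called over all genes and 7 were higher adjusted over the list alone (median 0.48, camera adjusted p = 1.07e-07; adjusted p = 0.023 with an estimated correlation). These 7, most of them named only after their values were seen, were Cpa3, the eosinophil granule genes Prg2 (3.66), Epx (at least 3.98-fold, SE 0.22, adjusted p = 0.0537 over all genes) and Prg3 (1.20), Prss34 (2.39), Ear6 (1.11) and Mcpt8 (1.07).

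Other lists had medians within 1 log2 unit of 0 with GSK343 and no called member. Cell cycle genes had a median of 0.68 (camera adjusted p = 4.37e-11; adjusted p = 0.871 with an estimated correlation; 0 of 26 adjusted over the list alone), with Kif11 at 0.88 and Mki67 at 0.58. Primary granule genes had a median of 0.73 (adjusted p = 0.000835, and 0.871 with an estimated correlation; 1 of 10 alone), and secondary granule genes −0.27 (adjusted p = 0.00144, and 0.871; 1 of 14 lower alone), although Lyz2 and Chil3 stood at the array ceiling in vehicle. Single members lay far from these medians without passing over all genes: Mmp8 was at 14.32 ± 0.06 against 18.23 ± 0.09 with vehicle (−3.90, SE 0.478, adjusted p = 0.119), the gelatinase gene Mmp9 at −2.91 (SE 0.403, adjusted p = 0.166) and Mpo at 2.64 (adjusted p = 0.346), all named after their values were seen. Gelatinase granule genes had a median of −0.30 (adjusted p = 0.000251, and 0.716 with an estimated correlation; 2 of 10 lower alone, Mmp9 and Retnlg), with Retnlg at −1.92 (adjusted p = 0.234), and migration receptors −0.25 (adjusted p = 0.0378, and 0.871; 0 of 15 alone). The other 23 lists were not called, including HOX genes and developmental transcription factors (medians 0.00 and 0.00), interferon-stimulated genes (−0.08) and erythroid markers (0.02). Counts of calls were 0 without GSK343 array 1, vehicle array 1 or vehicle array 2, and 2 without GSK343 array 2. At an unadjusted p under 0.05, limma listed 3963 clusters, where 3298 are expected by chance, and median centring of the arrays gave 8 calls (7 up, 1 down).

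Neutrophils labelled Ezh2-null and neutrophils given GSK343 were then set side by side, each against its own control. Cpa3 was the 1 shared call (0.0675 expected of independent lists, again over all clusters). The log2 fold changes correlated across clusters at Pearson r = 0.32 and Spearman rho = 0.25, without shared arrays. GSK343 values also correlated with wild-type differentiation (r = −0.42) and that of cells labelled Ezh2-null (−0.31), again without shared arrays. With genotype in undifferentiated cells r was 0.11. Whether the 0.32 goes beyond a shared run against differentiation was not tested. Clusters higher in neutrophils labelled Ezh2-null were positive with GSK343 in 78.3% of cases (48.1% of other clusters), with a median of 0.21. Against other clusters, camera with an estimated correlation gave adjusted p = 0.017 over 8 such sets, and against no change limma's fry gave adjusted p = 0.0157. Those lower were negative in 64.6% (49.1% of others; camera adjusted p = 0.192, fry adjusted p = 0.257). These 2 tests were chosen after seeing the data. The effects differed for 2177 clusters (1302 up, 875 down), among them Tpsb2 (11.61, SE 0.406, adjusted p = 1.63e-06), Rhag (10.26), Car2 (10.24), Aqp1 (9.52) and Ermap (8.92), and in the other direction Hpse (−7.36), Plbd1 (−6.20) and Pla2g7 (−6.08). Camera called 11 lists, including cell cycle (median 2.09, adjusted p = 7.49e-17), interferon-stimulated (2.49, adjusted p = 8.77e-18) and erythroid genes (1.81, adjusted p = 2.56e-09). With an estimated correlation these gave adjusted p = 0.353, 0.324 and 0.0523, and eosinophil, basophil and mast cell markers gave adjusted p = 0.0348. The count of 2177 fell to 947 without vehicle array 2, 1080 without vehicle array 1, 1099 without GSK343 array 2, 1176 without GSK343 array 1 and 1254 without labelled-null neutrophil array 2.

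Vehicle-treated and untreated wild-type neutrophils lie in the 2 array ranges, so their comparison is descriptive. Of all clusters, 45469 differed, 44304 of them lower with vehicle (median of all clusters −0.65). After quantile normalization over all arrays 12670 differed (7103 up, 5567 down), and after median centring 16369 (9296 up, 7073 down). Vehicle, culture and array range cannot be told apart here.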

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

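The interaction test of genotype and stage was planned; every test of an explanation in this part was chosen after the result was seen. The difference by genotype label changed between undifferentiated cells and neutrophils for 2911 clusters (limma interaction term, 2 arrays per group). In neutrophils relative to undifferentiated cells, this difference was higher by 12.17 log2 units for Cpa3, 11.55 for Tpsb2 and 11.11 for Mcpt8. It was higher by 11.06 for Car2, 9.93 for Rhag and 2.89 for Ezh2 itself. Mcpt8 and Ezh2 were lower in Ezh2-null undifferentiated cells, so part of their values comes from that stage. The difference went the other way for Plbd1 (−8.55), Angptl7 (−8.55), Maf (−5.95), Pltp (−5.52) and Lrg1 (−5.46). Angptl7 fell on differentiation of the Ezh2-null cells to at least 220.5-fold less, so its high level belonged to the undifferentiated stage.

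Camera called 9 lists for the same difference. The medians were 2.93 for cell cycle genes, 2.81 for interferon-stimulated genes, 2.43 for primary granule genes (4 of 10 called, 8 adjusted over the list alone), 1.27 for erythroid and megakaryocyte markers (6 of 12, 7 up and 1 down alone), 1.18 for eosinophil, basophil and mast cell markers and 0.84 for progenitor genes (7 up and 4 down of 20, 10 and 4 alone). They were −2.82 for secondary granule genes (1 up and 5 down of 14, 1 and 10 alone), −0.72 for NADPH oxidase genes (2 of 7, 3 alone) and −0.12 for HOX genes (1 of 33, 4 alone). With an estimated correlation the mast cell list held (adjusted p = 0.0151). The other 8 gave adjusted p = 0.299 for cell cycle and progenitor genes, 0.364 for interferon-stimulated and primary granule genes, 0.148 for erythroid markers, 0.505 for secondary granule, 0.425 for oxidase and 0.52 for HOX genes. Without wild-type undifferentiated array 1 the 2911 clusters became 1636, without array 2 1511, and without labelled-null neutrophil array 2 1610.

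Ezh2 was not lower in neutrophils labelled Ezh2-null (8.88 ± 0.19 against 8.33 ± 0.02). An exchange of the neutrophils' genotype labels would turn the shared changes around, but 85.6% of clusters higher in Ezh2-null undifferentiated cells had the same sign in neutrophils, among them Smo, Ryk and Tbx15. Ezh2 transcript could follow cell division, since cell cycle genes had a median of 2.74 in the same comparison with 24 of 26 members called. Probes outside the deleted exons could also keep a signal: Ezh2 in the null undifferentiated arrays lay 3.71 log2 units above background. This cannot be told apart from retained whole transcript, because the exons deleted and the values per probe are not in the sources used here.

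Mast cell and erythroid genes were higher in neutrophils labelled Ezh2-null. Carried-over undifferentiated cells cannot exceed their own level, yet 80% of the called members (16 of 20) were also called higher than in Ezh2-null undifferentiated cells. Il5ra, Tpsab1, Prss34 and Itga2b were the exceptions. The same 2 labelled-null neutrophil arrays chose these members and enter this comparison, so the share may be raised in part by the choice. A smaller neutrophil share stays open: monocyte markers had a median of −1.52, but they rise with wild-type differentiation itself (median 3.68), so their fall decides nothing. Mast or erythroid cells beside the neutrophils stay open too, as the labels name no sort. The 69.0% of measured members called higher (20 of 29) are the pattern itself, so they decide nothing. Cpa3 reached 19.10, though undifferentiated wild-type cells also held Cpa3 at 18.81. Mast or erythroid cells cannot be told apart from mast cell and erythroid genes expressed within neutrophils, because each array pools a culture. A different cell line per genotype stays open as well.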

How the results depend on the processing

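Crossed replicate numbers and the background baseline were tests chosen after the results were seen. The number of arrays (2 per group) and, for dim clusters, signal over background (28.8% to 43.4% of clusters above it) limit these results. In the genotype contrast in neutrophils, simulated 2-fold changes were recovered in 38% of cases, with 200 clusters changed. The real contrast called 7791 clusters, so its own recovery was not measured by this. No named call reversed direction with further quantile normalization, median centring, a trended robust variance, only the arrays of the contrast, the block, mean clusters or 1 array left out; other settings were not run for named genes. Where a value below moved, the cause was not tested unless fewer clusters or arrays were used.

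With fewer clusters tested, 1-symbol clusters gave 9 calls for GSK343 (1 with all), 10400 for wild-type differentiation (39.3% higher, 51.6% with all), 9167 for differentiation of cells labelled Ezh2-null, 23034 between vehicle and untreated neutrophils, and 7 calls shared by genotype label and GSK343. Leaving out dim clusters gave 29878 between vehicle and untreated neutrophils. Further quantile normalization gave 3 for GSK343 and 12670 for vehicle, and median centring 8 and 16369. A trended robust variance gave 3 for GSK343 and array weights (0.544 to 1.47) gave 15.

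With only the arrays of the contrast, 351 clusters were called for genotype in undifferentiated cells, 7591 for differentiation of cells labelled Ezh2-null and 1352 for the stage interaction. With only the same array range the counts were 1061 and 1352 for genotype in undifferentiated cells and the interaction. The replicate number as a block gave 7512 for genotype in neutrophils, 1831 in undifferentiated cells and 2 for GSK343. Crossed numbers gave 0 for GSK343 in limma (1 without a block), and at an unadjusted p under 0.05 4018 (3963 without a block). Same-number deviations correlated at 0.19 and 0.04 for genotype in neutrophils and undifferentiated cells, −0.19 for GSK343, and −0.11 and 0.10 for wild-type and null differentiation, which gave no ground for a block outside this setting.

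At an adjusted p under 0.01, 4239 clusters were called for genotype in neutrophils, 1010 in undifferentiated cells, 0 for GSK343 in limma (3963 at an unadjusted p under 0.05), 9088 for differentiation of cells labelled Ezh2-null, 1157 for the stage interaction and 901 for the drug interaction. At an unadjusted p under 0.05 with a 2-fold change the counts were 334 for GSK343, 9757 for that differentiation, 5045 and 4254 for the interactions and 17083 for vehicle. At an adjusted p under 0.1, genotype label and GSK343 shared 7 calls, and 3170 differentiation changes were smaller. The share of higher clusters with a low baseline was 14.4% at the 40th percentile, 26.5% at the 60th and 35.4% at background.

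Without 1 array, counts ranged from 4023 to 6319 for genotype in neutrophils (4023 without labelled-null array 2, 4922 without wild-type array 1), 962 to 2776 in undifferentiated cells (962 and 1060 without wild-type arrays 1 and 2) and 0 to 2 for GSK343. They ranged from 12543 to 13555 for wild-type and 10356 to 16463 for null differentiation. The stage interaction gave 1511 to 3758, with 1511 and 1636 without wild-type undifferentiated arrays 2 and 1 and 1610 without labelled-null neutrophil array 2. The drug interaction gave 947 to 2201, with 947 and 1080 without vehicle arrays 2 and 1, 1176 and 1099 without GSK343 arrays 1 and 2 and 1254 without labelled-null neutrophil array 2. Changes shared by the stages numbered 472 to 906 (472 and 497 without wild-type undifferentiated arrays 1 and 2), those shared with GSK343 0 to 1, and smaller differentiation changes 978 to 2485 (978 and 1058 without wild-type undifferentiated arrays 2 and 1, 1309 without wild-type neutrophil array 1, 992 without labelled-null neutrophil array 2). The low-baseline share ranged from 17.0% to 23.8%.

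Of 203 list tests camera called 77, against 10 with an estimated correlation, 84 with fry, 75 with the block, 70 without dim clusters and 77 with mean clusters.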

Other observations

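The gene families of the first 2 paragraphs and the test of slower differentiation were chosen after the results were seen; the power and signal-level tests had been set before. These families were picked because related genes had changed, so counts are given without a test of the family. In neutrophils labelled Ezh2-null, all 11 erythrocyte membrane genes were called higher than in wild-type neutrophils (median 6.32), among them Rhag, Aqp1 and Ermap, already named, the anion exchanger gene Slc4a1 (at least 73-fold, SE 0.109), the spectrin gene Sptb (at least 62.2-fold) and the blood group gene Kel (at least 37.7-fold). Haem synthesis genes were called higher in 6 of 8 cases (median 2.72), with Cpox at 6.39 and Alad at 4.32. Schlafen genes, which interferon induces, were called higher in 5 of 8 cases (median 2.19), with Slfn1 at 5.05 (SE 0.18) and Slfn4 at 3.67.

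Some genes of protein synthesis were higher in the same comparison. Cytosolic ribosomal genes were called higher in 26 of 42 cases and lower in 1, Rpl7l1 at −1.09 (median 1.05), with Rpl35 at 1.93 and Rps20 at 1.83. Aminoacyl-tRNA synthetase genes were called higher in 9 of 15 cases (median 1.13), with Hars at 1.98, and all 15 were called lower in wild-type differentiation (median −2.16). The immunoproteasome genes Psmb8 (−0.99) and Psmb9 (−0.82) fell while 5 of 38 proteasome genes rose. Among clusters changed in wild-type differentiation, 38.7% of those with 1 symbol and 72.9% of those without any symbol were higher; their mean signals were 6.10 and 4.98.

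GSK343 values ran against the differentiation response with 1 call. Clusters that fall in wild-type differentiation had a median of 0.18 with GSK343. This lay at percentile 100 of 10000 random sets matched on mean signal over all arrays (highest random median 0.04). Such clusters are brighter in undifferentiated cells than in neutrophils, so the match need not hold for their level on the drug arrays. Random sets also do not keep the correlation between the set's clusters (estimated at 0.0521). A trend with signal level therefore stays open. Low power may explain why 2-fold changes were missed beside the single call, Cpa3. In the simulation 46% of them were recovered, but there 200 clusters were changed. The adjusted p cutoff is stricter in a contrast with 1 call, so the 46% does not measure the power of this contrast. Larger values also went uncalled, such as Mmp8 at −3.90 (SE 0.478, adjusted p = 0.119), so the recovery of simulated 4-fold changes (98%) does not carry over to every gene. Slower differentiation under GSK343 stays open: the falling set was higher by limma's fry (adjusted p = 0.012), while the rising set, with a median of −0.14, gave adjusted p = 0.201. It cannot be told apart from a direct effect, because 1 time point was measured.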
